A study of Homo sapiens with 5 samples.

How the data were processed

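Gene expression in human TE85 osteosarcoma cells was measured after 32 hours on 5 culture surfaces, each on 1 Affymetrix array of the first human U133 set. The surfaces were taken from the sample titles, which do not say which of them are controls. Tissue culture polystyrene and the amino-terminated surface were treated here as the 2 controls. Surfaces conjugated with aspartic acid, glutamic acid or serine were the 3 amino acid surfaces. The values used were linear probe set intensities as deposited by the authors. The software, background correction and scaling behind those intensities are not given in the sources used here, and no detection calls were used. Deposited values ran from 12.4 to 18108.

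Array medians differed by 2.12% from lowest to highest, but 75th percentiles differed by 17.0%, more than the 10% set as the limit, so the arrays were quantile normalized. A floor was set at the 40th percentile of all scaled values (an intensity of 69.4), scaling came before the floor and the floor before log2. A gene was measured in a comparison where at least 1 of the arrays was above the floor. A value below the floor was set to it, and the ratio is then a bound. Of the probe sets, 19071 had 1 gene symbol, 1043 had several and 2101 had none. The last 2 kinds and 68 control probe sets were left out. Symbols came from GEO's platform table and were checked through Entrez gene identifiers against the RefSeq gene table of assembly GRCh38.p14, used for names only, in which 19059 probe sets matched and 0 symbols changed. The probe set with the highest mean over the 5 arrays stood for its gene, and 4310 genes had several.

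With 1 array per surface no test between surfaces was possible. All 10 pairs of arrays were compared by the log2 ratio of scaled intensities, with counts of genes at least 2-fold apart. The genes named were those with the 10 highest and 10 lowest log2 ratios in each comparison with the amino-terminated surface and between the controls, and the 5 highest and 5 lowest in each other comparison, leaving out ratios that are only bounds. For the class comparison they were the 10 with the widest gap in each direction, and up to 4 members of a list were named by the size of their log2 ratio. These are upper limits: fewer may be named, taken from the top. For the class comparison, genes were counted where all 3 amino acid arrays lay beyond both controls by at least 1.5-fold. For each of 41 gene lists fixed beforehand, holding 937 genes of which 119 matched no gene on the array, the median log2 ratio was ranked among 10000 random lists of the same size matched on mean level in 20 bins, where at least 5 genes were measured. A list is said to lie outside the random range when its median was below the 2.5th percentile of those lists or as far from the other end. This percentile describes these arrays and is not a p-value. A further 3 lists were added after the values were seen.

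Correlations between comparisons that share a control array were set beside 100 simulations of unchanged arrays. Every simulated array had the same spread at a given level, that of the aspartic acid and glutamic acid arrays. The procedure was tested on simulated arrays with the mean level of each probe set over the 5 arrays and the spread between the aspartic acid and glutamic acid arrays, the closest pair (up to 8405 genes, 5 runs, with 200 changed genes well above the floor). Of genes changed 1.5-fold, 2.5-fold, 3-fold and 4-fold, 0.4%, 96.8%, 99.2% and 100% were called at least 2-fold apart. Of unchanged genes 0 were 2-fold apart and 3 to 7 per run were 1.5-fold apart. A list shift of 0.3 was recovered as 0.23 to 0.31. Pairs with more spread, such as serine against amino-terminated (log2 ratio SD 0.29 against 0.15), were not simulated, so these rates do not carry over to them.

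The groups, comparisons, lists, naming rule and first set of alternatives were chosen before the data were examined. The alternatives were the values as deposited, equal medians, equal 75th percentiles, floors at the 25th and 60th percentiles, no floor, a pseudocount of 50 in place of the floor, the mean of all probe sets of a gene, thresholds of 1.5-fold and 3-fold, polystyrene as the control array and leaving out each array. Genes of above-median level and single arrays against the other 4 were added later. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.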

Results

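Gene expression was measured in TE85 cells, a human osteosarcoma line with osteoblast-like features, after 32 hours on 5 culture surfaces. The surfaces were tissue culture polystyrene, a surface ending in amino groups, and surfaces conjugated with aspartic acid, glutamic acid or serine. Each surface was measured on 1 Affymetrix human expression array, which gave 11963 named genes. There were no replicates, so no difference below has a replicate check, no p-value is given, and the number of arrays limits the precision. Between 8170 and 8228 genes per array lay above the intensity floor. The pair of arrays with the smallest spread, aspartic acid against glutamic acid, had a log2 ratio SD of 0.15 over 8397 genes, that of aspartic acid against amino-terminated was also 0.15, and the pair with the largest, serine against amino-terminated, had 0.29.

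Control probe sets read as signs of RNA quality differed between the arrays, while RNA quality itself was not measured. The 3' over 5' intensity ratio of ACTB was 0.996 on polystyrene, 1.22 on aspartic acid, 1.54 on amino-terminated, 1.62 on glutamic acid and 1.71 on serine, and that of GAPDH ran from 1.20 on polystyrene to 1.80 on serine. The 3' probe set of 28S ribosomal RNA read 7230 on the amino-terminated array and between 1090 and 1688 on the others. That of 18S ribosomal RNA read 9289 there and between 3768 and 6863 on the others. The geometric mean of the spiked control transcripts was 527 on aspartic acid, 699 on polystyrene, 786 on serine, 814 on glutamic acid and 1012 on amino-terminated.

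**Figure D1:**
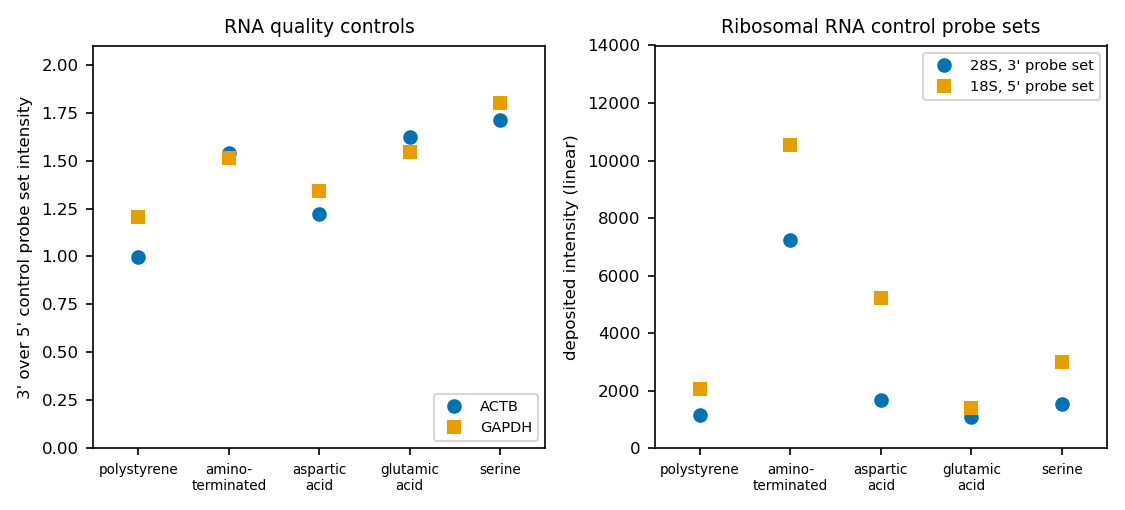
Left, 3' over 5' intensity ratio of the ACTB and GAPDH control probe sets on each array; right, deposited linear intensity of the 3' probe set of 28S and the 5' probe set of 18S ribosomal RNA; each point is 1 array. Polystyrene had the lowest ratios (0.996 and 1.20), and the amino-terminated array had the highest ribosomal RNA values (7230 and 10527).

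The comparison of the amino-terminated surface with tissue culture polystyrene set the 2 control surfaces against each other. GCLM, the modifier subunit of the first enzyme of glutathione synthesis, was the highest gene on the amino-terminated array, at 994 against 244 (log2 ratio 2.02). The transcription factor MAFF followed at 1.94, but its other probe set gave 0.32. Next came the ERK phosphatase DUSP6 (1.74), the cystine-glutamate exchanger SLC7A11, at 868 against 274 (1.66), the transcription factor ETV5 (1.37), TRIM16 (1.33), SECISBP2L (1.31), the asparagine synthetase ASNS (1.27) and the actin regulator WASL (1.19). The other probe set of SECISBP2L gave 0.48. GOLIM4 had 1.16 with −0.57 from its other probe set. Lower genes were led by ACTA2, smooth muscle actin, at 160 against 420 (−1.39), then an uncharacterized locus, the natriuretic peptide NPPB (−1.06), TMEM230 (−1.01), the orphan receptor GPR176 (−0.93), the folate receptor FOLR1 (−0.90), LRRC17 (−0.90), the bone morphogenetic protein BMP4 (−0.88), KLF5 (−0.86) and OLFML3 (−0.84).

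By group, 22 of 27 measured amino acid response genes (targets of ATF4) were higher and 8 of them by at least 1.5-fold. The list's median log2 ratio was 0.33, above every one of the matched random lists. PSPH, of serine synthesis, stood at 0.93, and VEGFA at 0.92, with its other probe sets between −0.07 and 0.03. Of 35 genes of G2/M and mitosis, 28 were higher (median 0.19, percentile 99.99), with AURKA at 0.74, BUB1 at 0.56, and CDK1 at 0.55 although its other probe sets gave −0.50 and −0.44. Immediate early genes had a median of 0.20 (percentile 99.8) with 12 of 19 higher, including EGR1 (0.95), and 8 of 9 metallothionein-list genes were higher (median 0.16, percentile 98.0), led by SLC30A1 (0.34) and MT1F (0.32). Among genes encoding contractile proteins and other SRF targets, 16 of 19 were lower (median −0.26, below all random lists), with ACTG2 at −0.70, MYL9 at −0.65 and TPM1 at −0.50. Of the matrix lists, 3 lay below the random range. Lower were 12 of 15 collagens (median −0.17, percentile 0.72, COL3A1 −0.83, COL1A2 −0.71, COL5A2 −0.44) and 13 of 15 genes of collagen processing (median −0.23, percentile 0.04, LOXL1 −0.45, LOXL2 −0.34), as were 7 of 9 genes of osteoblast differentiation and bone matrix (median −0.33, percentile 0.04), in which MSX1 (0.66) went the other way and SPARC stood at −0.40. The 25 non-collagen matrix genes lay inside the random range (17 lower, median −0.10, percentile 6.95).

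Oxidative stress genes (NRF2 targets) had a median of 0.19 (percentile 99.8) with 13 of 19 higher and 5 by at least 1.5-fold, among them ME1 (0.83) and NQO1 (0.83), but 6 of 9 processing alternatives put the median inside the range of random lists. CDK inhibitors and growth arrest genes (median 0.33, percentile 99.97, RB1 0.60, GAS1 0.58) and glycolysis genes (median −0.11, percentile 2.34, ENO2 −0.48, PFKM −0.31) lost their place outside that range under 4 of 9 alternatives each, and the bone matrix list under 1. In all, 17 genes were at least 2-fold higher and 4 at least 2-fold lower among 8474 genes, and the split was 25 and 1 on the values as deposited and 27 and 1 with equal medians. The 3' over 5' ratios and the ribosomal RNA control also differed between these arrays, as given above.

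**Figure D2:**
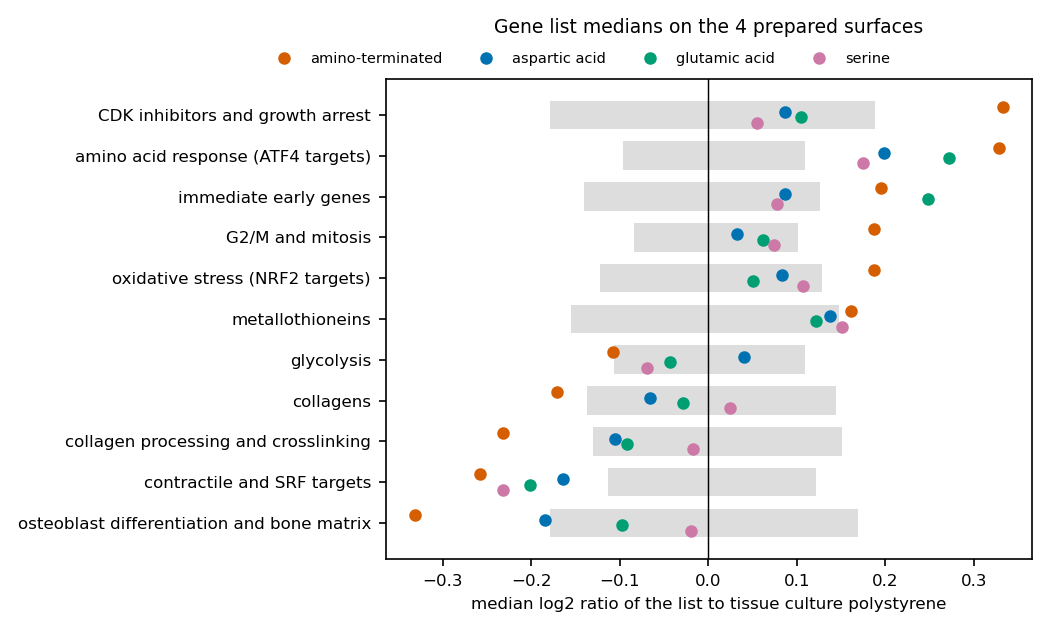
Median log2 ratio to tissue culture polystyrene (x axis) of 11 gene lists (y axis) on the 4 prepared surfaces, 1 point per array, for the lists outside the random range on the amino-terminated array; grey bars give the central range of random lists matched to that array's comparison. The amino acid response list lay above 0 on all 4 arrays (0.17 to 0.33) and the contractile list below 0 (−0.26 to −0.16).

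The 3 amino acid surfaces were next compared with the amino-terminated control, beginning with aspartic acid. GPNMB, a membrane glycoprotein of lysosome-related organelles, was highest at 1283 against 691 (log2 ratio 0.89), followed by the matricellular gene CCN3 (0.78), UAP1L1 (0.74), the lysosomal sialidase NEU1 (0.71), MTUS1 (0.67), the pseudogene OR7E14P (0.67), the enolase ENO2 (0.61), the lysosomal peptidase TPP1 (0.61), RRAGC (0.61) and GNPDA1 (0.60). Other probe sets gave 0.30 for CCN3, 0.12 to 0.30 for MTUS1 and 0.21 to 0.44 for TPP1. The lowest were ASNS (−0.87), the matricellular gene CCN2 (−0.83), MAFF (−0.82, with −0.41 from its other probe set), SLC7A11 (−0.77), FIP1L1 (−0.76), GCLM (−0.70) and THBS1, thrombospondin 1 (−0.64, with other probe sets from −0.49 to −0.12). No gene reached 2-fold among 8322, and 13 were higher and 10 lower by at least 1.5-fold. That split was 10 and 13 on the values as deposited, 7 and 13 with equal medians and 11 and 11 with equal 75th percentiles. Amino acid response genes (21 of 27 lower, median −0.14) and genes of G2/M and mitosis (28 of 35 lower, median −0.17) lay below all random lists, and outside the random range under each of 9 alternatives, with MTHFD2 and PCK2 at −0.49 each, CCNB1 at −0.40 and MAD2L1 at −0.37. Glycolysis genes were higher in 17 of 18 cases (median 0.14, percentile 99.8, PFKM 0.41), also outside the random range under each of 9 alternatives.

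Several further lists left the random range on aspartic acid against amino-terminated under fewer settings. Immediate early genes (median −0.18, percentile 0, DUSP6 −0.41 with another probe set at 0.00, DUSP1 0.36), cholesterol genes (0.14, percentile 99.9, EBP 0.40 with other probe sets from −0.19 to 0.02, INSIG1 0.34), chaperones of the endoplasmic reticulum (−0.08, percentile 1.11, XBP1 −0.47, HSP90B1 −0.37) and genes of G1/S and DNA replication (0.08, percentile 97.7, MCM4 0.33 with other probe sets from −0.34 to 0.13, POLD1 0.32) did so in 8 of 9 alternatives. Heat shock proteins (−0.07, percentile 2.30, BAG3 −0.25) and hypoxia-inducible genes (0.10, percentile 98.8, BHLHE40 0.52) did so in 7 of 9. YAP and TEAD targets (−0.10, percentile 0.80, F3 −0.38) did so in 6, and BMP and ID genes (0.15, percentile 99.8, BMP4 0.47, GREM1 0.43) in 5 of 8. CDK inhibitors (−0.14, percentile 0.30, RB1 −0.52, CDKN1A −0.50) changed sign in 4 of 9. Oxidative phosphorylation (0.09, percentile 98.0, although COX7A2 stood at −0.35) and interferon-stimulated genes (0.11, percentile 99.96, IFITM3 0.30) returned to the random range in 5 and 6 of 9.

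On the glutamic acid surface, against the amino-terminated surface, GPNMB was again the highest gene at 1232 against 691 (log2 ratio 0.83). The creatine transporter SLC6A8 (0.77), CELP (0.75), VNN3P (0.72), GABRB2 (0.71), GNPDA1 (0.70), CCN3 (0.70), FOLR1 (0.70), TNFAIP3, an inhibitor of NF-kB signalling (0.68), and the hypoxia-inducible factor EPAS1 (0.67) followed. Other probe sets gave 0.31 to 0.36 for SLC6A8 and 0.25 for CCN3. On amino-terminated, CELP and VNN3P read 78.9 and 70.8, close to the floor of 69.4. GCLM (−0.74), LRIF1 (−0.72), CCN2 (−0.71), SECISBP2L (−0.67, with −0.15 from its other probe set), ASNS (−0.65), OPN3 (−0.65) and SLC7A11 (−0.64) were lowest. Amino acid response genes (20 of 27 lower, median −0.16, PSAT1, of serine synthesis, −0.59), G2/M genes (28 of 35 lower, median −0.15, HMMR −0.49, CKS2 −0.42), heat shock proteins (13 of 16 lower, median −0.09, percentile 0.03, BAG3 −0.37, DNAJB1 −0.28) and proteasome subunits (19 of 26 lower, median −0.07, percentile 0, PSMC6 −0.41) lay below the random range under each of 9 alternatives. No gene of 8392 reached 2-fold, and 22 were higher and 14 lower by at least 1.5-fold. The split was 21 and 27 both on the values as deposited and with equal medians, and 41 and 11 with equal 75th percentiles.

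Of the matrix lists, 3 were higher on glutamic acid than on amino-terminated. These were 11 of 15 collagens (median 0.14, percentile 99.8, COL13A1 0.45 and COL1A1 0.33, each with another probe set below 0), 14 of 15 collagen processing genes (0.13, percentile 99.6, PLOD3 0.26) and 9 of 10 bone matrix genes (0.14, percentile 99.2, BMP4 0.44). Those calls held in 8, 5 and 7 of 9 alternatives, and all 3 were lost with the mean of all probe sets. The collagen and bone matrix lists share members such as COL1A2, so they are not separate signs. The 25 non-collagen matrix genes lay inside the random range (18 higher, median 0.06, percentile 82.8). Contractile genes (0.09, percentile 99.1, ACTG2 0.38), NF-kB targets (0.17, percentile 99.2, TNFAIP3 0.68, CSF3 0.42, ICAM1 0.40) and G1/S genes (0.07, percentile 97.7, POLE 0.24) lay above random lists, and kept that place in 7 of 9, 6 of 8 and 5 of 9 alternatives. Apoptosis regulators (−0.09, percentile 0.78, PMAIP1 −0.29, BAX −0.26) and oxidative phosphorylation (−0.03, percentile 1.16, NDUFS4 −0.21) lay below them, and in 8 of 9 alternatives each.

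The serine surface against the amino-terminated surface had 20 genes at least 2-fold higher and 9 at least 2-fold lower of 8588, the most of the 10 pairs at the main setting, but this split turned with the scaling: 9 and 26 on the values as deposited, 10 and 25 with equal medians, and 40 and 3 with equal 75th percentiles. The first place was lost to the pair of controls with the floor at the 60th percentile (7 genes against 16), with log2(value + 50) (3 against 9), at 3-fold (0 against 4) and among genes of above-median level (5 against 12, and 71 against 115 at 1.5-fold). The highest were VNN3P at 207 against 70.8 (log2 ratio 1.55), the chitinase-like protein CHI3L1 (1.42), LILRA5 (1.30) and IRF5 (1.21 with 0.36 from its other probe set). VSIG4 (1.17), the antisense gene IGF2-AS (1.11) and JRK (1.11 with other probe sets from 0.21 to 0.39) followed. On amino-terminated, CHI3L1, LILRA5, VSIG4 and IGF2-AS read 71.0, 73.5, 74.9 and 80.3, and VNN3P was as dim, all close to the floor of 69.4. The lowest were MAFF (−1.55 with −0.40 from its other probe set), CCN2 at 1267 against 2887 (−1.19), PSPH (−1.12), ASNS (−1.09), EMC2 (−1.04) and CEBPG (−1.01). PSPH read 74.8 on serine, also close to the floor. Immediate early genes (14 of 19 lower, median −0.31, below all random lists, DUSP6 −0.86, DUSP4 −0.73, JUNB −0.67), amino acid response genes (21 of 27 lower, median −0.15, percentile 0.01, SLC7A11 −0.64) and G2/M genes (27 of 35 lower, median −0.14, HMMR −0.50) kept their place under each of 9 alternatives. Against the same array, 7 of 9 bone matrix genes were higher (0.28, percentile 99.6, BMP4 0.86). So were 11 of 15 collagens (0.19, percentile 99.6, COL13A1 0.65 with other probe sets from −0.27 to 0.29, COL1A2 0.35). Each of these calls held in 8 of 9 alternatives and was lost with the mean of all probe sets.

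The median log2 ratio of all genes for serine against amino-terminated moved from 0.02 to −0.12 on the values as deposited and to 0.10 with equal 75th percentiles, and list values are read against that shift. Collagen processing genes (0.15, percentile 99.3, PCOLCE 0.45) had a median of −0.05 on the deposited values and −0.04 with equal medians while still above the random range, and proteasome subunits (−0.05, percentile 1.26, PSMC6 −0.40) had 0.05 with equal 75th percentiles while still below that range, a place lost with the mean of all probe sets. CDK inhibitors (−0.20, percentile 1.49, TOB1 −0.53) left the random range in only 1 of 9 alternatives.

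Amino acid response genes and G2/M genes thus lay below random lists in all 3 comparisons with the amino-terminated array. Against polystyrene, however, G2/M genes lay inside the random range on aspartic acid, glutamic acid and serine (percentiles 60.1, 85.7 and 88.2). Only on amino-terminated did they lie above it (99.99). Collagens likewise lay inside it on glutamic acid and serine (18.1 and 44.3) and below it on amino-terminated (0.72). The 3 comparisons with the amino-terminated array share that array. The log2 ratios of the 3 surfaces correlated across genes with r between 0.49 and 0.79, where unchanged arrays set against 1 shared array gave 0.50 in simulation, and the covariance was between 0.015 and 0.039 against a simulated 0.011. All simulated arrays had the spread of the aspartic acid and glutamic acid arrays, the closest pair. A noisier shared array alone would raise both the covariance and r, so the excess does not show a shared change. Genes are not independent replicates, the shared array could not be split, and part or all of the excess may come from it.

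**Figure D3:**
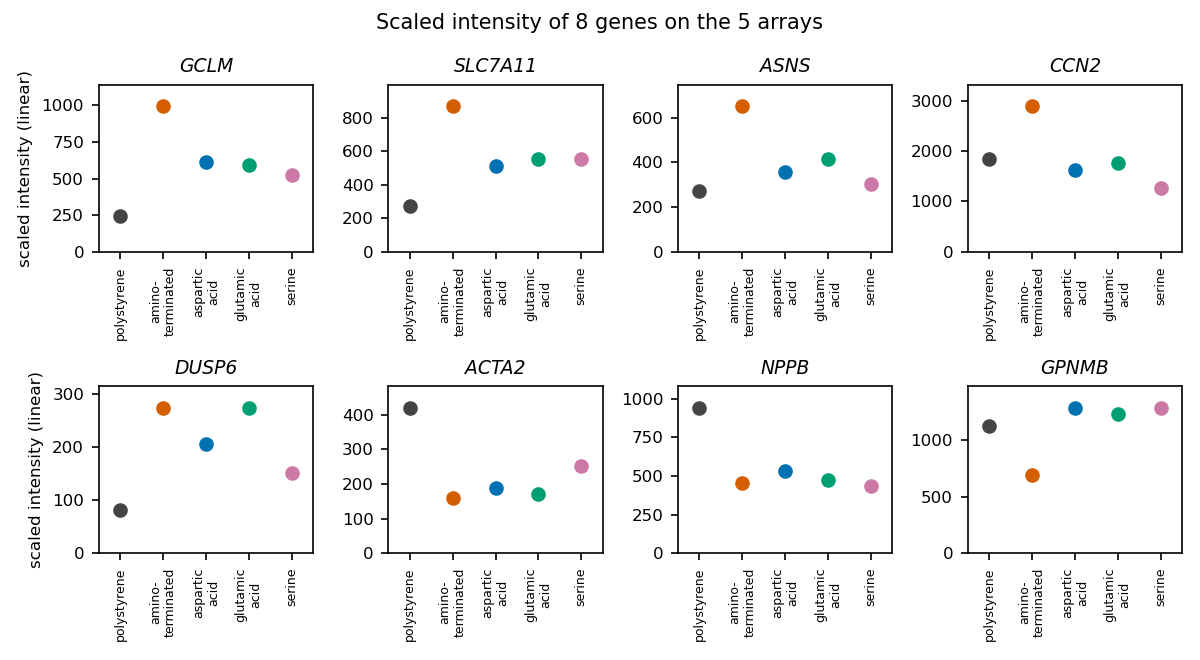
Scaled linear intensity (y axis) of 8 genes on the 5 arrays, 1 point per array and no error bars because each surface had 1 array. GCLM and SLC7A11 were lowest on polystyrene (244 and 274) and highest on amino-terminated (994 and 868), ACTA2 was highest on polystyrene (420), and GPNMB was lowest on amino-terminated (691).

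Against tissue culture polystyrene, the aspartic acid array was led by DUSP6 (log2 ratio 1.33), GCLM (1.33), MAFF (1.13, with −0.09 from its other probe set), TRIM16 (1.07) and the collagenase MMP1 (1.02). It was lowest for ACTA2 (−1.15), CELP (−0.89), GPR176 (−0.84), TMEM230 (−0.84) and NPPB (−0.83). The glutamic acid array was led by DUSP6 (1.73), MAFF (1.67, with 0.24 from its other probe set), GCLM (1.29), MMP1 (1.27) and ETV5 (1.11). It was lowest for EXOC5 (−1.31), ACTA2 (−1.29), GPR176 (−1.18), TMEM230 (−1.11) and PSAT1 (−1.05). On serine, GCLM (1.11), SLC7A11 (1.02), TRIM16 (0.95), DUSP6 (0.88, with other probe sets from 0.08 to 0.79) and VNN3P (0.87) were highest. Lowest there were GPR176 (−1.30), CAPN7 (−1.13, with −0.19 from its other probe set), NPPB (−1.12), GDE1 (−1.09) and GLE1 (−1.09). CELP on aspartic acid (75.7), EXOC5 on glutamic acid (75.1) and GLE1 on serine (75.2) were close to the floor of 69.4. At least 2-fold higher and lower genes numbered 6 and 1 on aspartic acid, 7 and 6 on glutamic acid, and 2 and 11 on serine.

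Amino acid response genes were above random lists on every prepared surface, with 22 of 27 measured genes higher than on polystyrene each time and medians of 0.20 on aspartic acid, 0.27 on glutamic acid and 0.17 on serine. PSAT1, a member of that list, was lower on all 3 (−0.67, −1.05 and −1.02). Contractile genes were below random lists on all 3, with 14, 15 and 15 of 19 lower and medians of −0.16, −0.20 and −0.23. ACTA2 stood at −0.73 on serine and MYL9 between −0.63 and −0.45. Both lists kept their place under each of 9 alternatives. The polystyrene array also had the lowest 3' over 5' ratios. The log2 ratios of pairs of prepared surfaces to polystyrene correlated across genes with r between 0.28 and 0.82 (simulated 0.50). Below the simulated value were serine with aspartic acid (0.31) and serine with amino-terminated (0.28). The covariance was between 0.014 and 0.046 (simulated 0.011). The simulated spread was that of the closest pair, and a noisier polystyrene array alone would raise the covariance. Part or all of the excess may come from this single shared array.

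Other lists left the random range for particular surfaces against polystyrene. Aspartic acid had higher fatty acid synthesis genes (11 of 13, median 0.19, percentile 99.8, ELOVL6 0.68, ACSL1 0.59), metallothioneins (0.14, percentile 98.2, MT3 −0.39, MT1X 0.37), hypoxia-inducible genes (0.13, percentile 98.6, BHLHE40 0.67) and matrix proteases and inhibitors (0.12, percentile 97.7, MMP1 1.02, PLAUR 0.54). It had lower collagen processing (−0.10, percentile 0.85, LOXL1 −0.32), bone matrix (−0.18, percentile 0.45, COL1A2 −0.43, but MSX1 0.65) and endoplasmic reticulum chaperone genes (−0.08, percentile 1.61, HSPA5 −0.29, but DNAJB9 0.39). Glutamic acid had higher immediate early genes (13 of 19, median 0.25, above all random lists, EGR1 0.73, FOSL1 0.68) and integrins (10 of 12, 0.14, percentile 97.7, ITGA5 0.43). Collagen processing (−0.09, percentile 1.65, LOXL1 −0.32), non-collagen matrix (−0.08, percentile 0.91, FN1 −0.45, BGN 0.46), BMP and ID (−0.14, percentile 0.59, BMP4 −0.44, HEY1 0.58) and oxidative phosphorylation genes (−0.05, percentile 2.44, COX5B −0.31 with other probe sets from −0.32 to 0.23) were lower on glutamic acid. Serine had higher matrix proteases and inhibitors (0.18, percentile 99.8, MMP1 0.77, ADAM12 at most −0.67 with other probe sets from −0.11 to 0.09, TIMP3 −0.63) and amino acid transporters (13 of 16, 0.17, percentile 99.3, SLC36A1 0.34), and lower oxidative phosphorylation genes (23 of 35, −0.05, percentile 1.42, ATP5F1A −0.29, but NDUFB8 0.30 with −0.23 from its other probe set). Collagen processing on aspartic acid and oxidative phosphorylation on serine held under all 9 alternatives. On aspartic acid, matrix proteases returned to the random range under 4 of 9, bone matrix and hypoxia-inducible genes under 3, fatty acid synthesis and chaperones under 2 and metallothioneins under 1. On glutamic acid, oxidative phosphorylation did so under 5 of 9, BMP and ID genes under 4 of 8 with a change of sign in 2, integrins under 3 of 9, non-collagen matrix genes under 2 with a change of sign in 1, and collagen processing and immediate early genes under 1. On serine, amino acid transporters did so under 4 and matrix proteases under 3.

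The amino acid surfaces were then set against one another. Aspartic acid and glutamic acid differ by 1 methylene group in the side chain, and serine carries a hydroxyl group where aspartic acid has its side chain carboxyl. Between the 2 acids no gene of 8397 reached 2-fold, as between either of them and the amino-terminated array, and 3 were higher and 6 lower on aspartic acid by at least 1.5-fold. That split was 6 and 6 on the values as deposited and 6 and 7 with equal medians. EIF5A (0.68, with other probe sets from −0.19 to 0.08), GMCL1 (0.62) and RMND1 (0.62) were highest and CELP (−0.81), ADAM28 (−0.70) and VNN3P (−0.65) lowest. Close to the floor of 69.4 were CELP and VNN3P on aspartic acid (75.7 and 74.3) and RMND1 on glutamic acid (77.1). Without replicates no interval of a difference can be given, so the lack of 2-fold genes does not show that the surfaces act alike. Cholesterol genes were higher on aspartic acid in 15 of 17 cases (median 0.14, above all random lists, NSDHL 0.44, INSIG1 0.44), oxidative phosphorylation in 29 of 35 (0.07, percentile 99.8, ATP5F1B 0.30) and interferon-stimulated genes in 19 of 23 (0.11, percentile 99.9, IFI35 0.39). NF-kB targets were lower in 11 of 13 (−0.17, percentile 0.24, TNFAIP3 −0.49, RELB −0.27). These calls held under every alternative, apart from that of the interferon list among brighter genes. Integrins (−0.10, percentile 1.58, ITGB1 −0.31), YAP and TEAD targets (−0.09, percentile 2, AMOTL2 −0.24) and ribosome biogenesis genes (−0.07, percentile 2.49, POLR1B −0.36) lost theirs under 5, 4 and 3 of 9.

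Serine differed more from aspartic acid than from glutamic acid, with 15 and 1 genes at least 2-fold apart and 310 and 70 at least 1.5-fold apart, yet 21 and 4 of the latter were genes of above-median level. The order at 2-fold did not hold among those genes or with the floor at the 60th percentile (0 and 1 genes each time), and log2(value + 50) gave 2 and 1. Aspartic acid over serine was highest for EMC2 (0.98), GLE1 (0.97) and GMCL1 (0.94). It was lowest for VNN3P (−1.48), MEF2D (−1.21, with 0.14 from its other probe set) and KRT76 (−1.16). Close to the floor of 69.4 were VNN3P, MEF2D and KRT76 on aspartic acid (74.3, 73.2 and 71.2). So were GLE1 and GMCL1 on serine (75.2 and 72.6). No gene was 2-fold higher and 15 were 2-fold lower, a split of 3 and 9 on the values as deposited and of 1 and 9 with equal medians, where the median of all genes shifted to 0.13 and 0.10. Glutamic acid over serine was highest for MAFF (1.27, with 0.32 from its other probe set), DUSP6 (0.85) and TNFAIP3 (0.80) and lowest for CHI3L1 (−0.94), VSIG4 (−0.91) and VNN3P (−0.83). Immediate early genes were lower on serine than on either acid, 14 of 19 each time, with medians of 0.18 for aspartic acid over serine (percentile 99.9, DUSP5 0.58, JUNB 0.50) and 0.22 for glutamic acid over serine (percentile 99.99, JUNB 0.71). Both calls ended with the floor at the 60th percentile. Glycolysis genes were higher on aspartic acid than on serine in 16 of 18 cases (0.09, percentile 98.6, GPI 0.29), a call lost with the mean of all probe sets. For aspartic acid against serine only these 2 of 40 lists lay outside the random range, and 2 lie there by construction. Cholesterol genes were lower on glutamic acid than on serine in 15 of 17 (−0.11, percentile 0.82, INSIG1 −0.65), under all 9 alternatives. All 6 measured adipocyte markers were lower as well (−0.24, percentile 1.78, PPARG −0.35), a call lost under 2 of 7 alternatives. NRF2 targets (−0.11, percentile 0.07, GPX2 −0.44) and oxidative phosphorylation (−0.05, percentile 0.66, NDUFB3 −0.25) were lower at the main setting. Their medians were 0.03 and 0.09 on the deposited values and 0.02 and 0.08 with equal medians, where the median of all genes shifted to 0.10 and 0.09. The NRF2 list stayed below the random range under both scalings and returned to it under 3 other alternatives, and oxidative phosphorylation returned to it under these 2 and 2 more.

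The series title sets the amino acid surfaces as a class against the controls. The largest gaps between the 3 amino acid arrays and both controls were those of CCN3, which read 156 to 167 on the amino acid arrays against 97.2 and 107 (gap 1.46-fold), NAV2 (1.31-fold), the chromatin protein HMGA2 (1.26-fold), MAPKAPK3 (1.25-fold) and STX3 (1.23-fold), higher on the amino acid surfaces. The other probe set of CCN3 gave smaller log2 ratios to amino-terminated, 0.30 against 0.78 on aspartic acid and 0.25 against 0.70 on glutamic acid. Lower on the amino acid surfaces were FILIP1L (1.29-fold), RSL24D1 (1.23-fold), CTSZ (1.22-fold) and CLDND1 (1.21-fold). No gene had all 3 amino acid arrays beyond both controls by 1.5-fold. With any gap, 855 genes lay above and 489 below both controls. Both directions together made 15.4% of 8726 genes, where chance order gives 10% in each direction, so neither direction exceeded chance. The other splits of the arrays into 3 and 2 gave between 10.9% and 35.1%. Without the polystyrene array 9 genes passed the 1.5-fold gap, and without the amino-terminated array 26 did. With 1 control left, such counts include that array's own deviation. Polystyrene alone held 23 genes and amino-terminated 7 beyond all other arrays by that gap.

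Over all 10 comparisons, 81 of 394 list medians lay outside the random range, where between 1.95 and 2 lists per comparison lie there by construction. The number ran from 2 for aspartic acid against serine, no more than by construction, to 14 for aspartic acid against amino-terminated. Genes of a list vary together, so the excess is a description of these arrays and not a test. Lists for focal adhesion and actin linkers, ribosomal proteins, TGF-beta targets and Wnt components lay inside the random range in every comparison in which they were measured. So did replication-dependent histones, cadherins and junctions, and markers of epithelial, blood, cartilage and skeletal muscle cells. Lists inside the range were examined at the main setting only. Endothelial markers had fewer than 5 measured genes in each comparison.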

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

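The tests of dim probe sets for serine and of the 3' over 5' order for the amino acid response and oxidative stress lists were chosen only after the results were seen, as were the comparisons with genes higher on serine and with aspartic acid in the test of RNA quality. With 1 array per surface, none of the differences between surfaces in the next paragraph was tested.

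Oxidative phosphorylation genes had a median log2 ratio to the amino-terminated array of 0.086 on aspartic acid and −0.0336 on glutamic acid, in opposite directions. Against polystyrene, CHI3L1 was higher on serine (0.613) and lower on aspartic acid (−0.8392) and amino-terminated (−0.8062). VNN3P was likewise higher on serine (0.8665) and lower on aspartic acid (−0.6145) and amino-terminated (−0.6834). LILRA5 was higher on serine (0.6144) and lower on amino-terminated (−0.6871). The scaled intensities behind these lower ratios lay just above the intensity floor. On amino-terminated VNN3P read 70.8, CHI3L1 71.0 and LILRA5 73.5, and on aspartic acid VNN3P read 74.3. On serine the same genes read 207, 190 and 181. How much of these differences comes from spread among dim probe sets stays open. Among control probe sets outside the comparisons, the 3' and 5' probe sets of 28S ribosomal RNA read 4.2821 and 4.4287 times as high on the amino-terminated array as on the next highest array, and those of 18S ribosomal RNA 1.3536 and 2.0146 times.

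At the main setting the serine and amino-terminated arrays held the most genes apart, but among genes of above-median level the 2 controls held more (12 against 5 at 2-fold and 115 against 71 at 1.5-fold). On the values as deposited this pair still had the most genes at least 1.5-fold apart of all pairs, 656 (171 higher and 485 lower). There the median of all genes was −0.12, and the split turned to 486 and 111 with equal 75th percentiles. The serine array had the lowest deposited 75th percentile (263) and the amino-terminated array the highest (308). A difference of scale between these arrays could give that rank, so it does not decide whether quantile normalization was the whole source. Probe sets below the floor on all 5 arrays spread most between these arrays (SD of the log2 ratio 0.2752, rank 1 of 10 pairs), while among the brightest genes this pair ranked 4 (SD 0.174). Spread among dim probe sets may therefore account for much of this count and for its rank. A surface effect on the brighter genes stays open.

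Genes lower on glutamic acid and serine than on polystyrene may reflect shorter labelled RNA. Falling levels in the order of the 3' over 5' control ratios were found in 115 of 1588 probe sets, rank 3 of 120 possible orders, with a mean of 13.2 and at most 197 per order. Values tied at the floor took a fixed order in which glutamic acid came before serine. Probe sets with both at the floor could therefore enter the 115, which may be too high. The further probe sets of genes at least 1.5-fold lower on serine decide nothing, since their median log2 ratio of −0.1825 against −0.68 for the first ones (19 probe sets of 14 genes) was matched among genes at least 1.5-fold higher by 0.16 against 0.65 (37 of 26), as picking genes by the first probe set gives. Over 29 genes low on both arrays the median was −0.75 on glutamic acid and −0.5818 on amino-terminated, close enough to meet the bound set in advance for RNA quality, but also −0.49 on aspartic acid, whose mean 3' over 5' ratio (1.28) was nearer to polystyrene's (1.10) than that of amino-terminated (1.53), so this too leaves RNA quality open. All these ratios share the polystyrene array, so a surface effect and that array's own deviation stay open.

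Amino acid response genes were higher on the amino-terminated array than on the other 4, whereas oxidative stress genes on that array lay outside the random range only against polystyrene. The amino acid response list was lower on glutamic acid and serine than on amino-terminated (median −0.152 on serine). Their mean 3' over 5' ratios were higher, 1.58 and 1.76 against 1.53. Among these arrays the list thus did not rise with the ratio, but that is part of the pattern itself and no separate test. Polystyrene had the lowest mean ratio (1.10) and was lower for this list than the other 4 arrays. A part played by shorter labelled RNA therefore stays open. For the oxidative stress list the median of serine over amino-terminated was −0.001, inside the random range, which decides nothing. Dim probe sets are argued against by the brighter members of both lists (23 genes, median 0.2538 over polystyrene, above all random lists). An effect of the surface is one hypothesis. The high ribosomal RNA signal of that array and its lack of a replicate could also matter and were not tested.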

How the results depend on the processing

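Genes of above-median level and the single-array counts were chosen after seeing the data. No paired analysis was possible because each surface has 1 array. Only the 95 list medians outside the random range at the main setting, with those of the added lists, were recomputed under the alternatives. Lists inside the range were not, so none of them could leave it. Apart from the change of control, 697 of 849 recomputed list medians kept their direction and their place outside the random range, 136 returned to that range and 16 changed sign. Of these 16, 9 arose in comparisons of serine with another scaling, which moved the median of all genes the same way, and 5 of the 9 stayed outside the random range on their former side. The other 7 fell inside it. In addition, 3406 of 3781 named gene values moved by less than the SD of log2 ratios between the 2 acids (0.15), and 69 of 110 counts of 2-fold genes stayed within 1.5 times. Signal over background limits the counts of dim genes, which were higher without a floor in the comparisons given below. The cause of the other values below was not tested.

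With polystyrene as the control array, which replaces the denominator, only 3 of 42 list medians kept their direction and place, 16 returned to the random range and 23 changed sign. The medians that changed sign were, for aspartic acid, 0.033 for G2/M, 0.087 for CDK inhibitors, 0.087 for immediate early genes and 0.20 for amino acid response. They were −0.039 for BMP and ID genes, −0.00046 for vacuolar ATPase and 0.27 for ERK-dependent genes. For glutamic acid they were −0.10 for bone matrix, −0.029 for collagens, −0.092 for collagen processing, −0.20 for contractile genes, 0.061 for G2/M, 0.27 for amino acid response and −0.062 for vacuolar ATPase. For serine they were −0.020 for bone matrix, −0.017 for collagen processing, 0.075 for G2/M, 0.055 for CDK inhibitors, 0.078 for immediate early genes, 0.17 for amino acid response, 0.021 for proteasome, −0.048 for vacuolar ATPase and 0.18 for ERK-dependent genes.

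On the values as deposited, serine against amino-terminated gave −0.050 for collagen processing and −0.067 for vacuolar ATPase, the NRF2 list between the controls 0.19, and glutamic acid against serine 0.085 for oxidative phosphorylation and 0.026 for NRF2 targets. With equal medians these 5 values were −0.042, −0.059, 0.21, 0.077 and 0.018. With equal 75th percentiles the proteasome list was 0.052 for serine against amino-terminated, the NRF2 list 0.071 between the controls, and 8 and 29 genes were 2-fold apart for serine against polystyrene and aspartic acid against serine.

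With the floor at the 25th percentile, CDK inhibitors were 0.013 for aspartic acid against amino-terminated, and 53 and 27 genes were 2-fold apart for serine against amino-terminated and aspartic acid against serine. At the 60th percentile, 7 genes were 2-fold apart for serine against amino-terminated, 4 for aspartic acid and 7 for serine against polystyrene, and 0 for aspartic acid against serine, and the non-collagen matrix list was 0.030 for glutamic acid against polystyrene. Without a floor, CDK inhibitors were 0.0076 for aspartic acid against amino-terminated, the NRF2 list 0.092 between the controls and BMP and ID genes 0.0084 for glutamic acid against polystyrene, with 69, 32 and 37 genes 2-fold apart for serine against amino-terminated, between the controls and for aspartic acid against serine.

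With log2(value + 50), which shrinks ratios of dim genes, CDK inhibitors were 0.0026 for aspartic acid against amino-terminated, bone matrix −0.046 and NRF2 targets 0.072 between the controls, and BMP and ID genes 0.0040 for glutamic acid against polystyrene. Genes 2-fold apart then numbered 3 for serine against amino-terminated, 9 between the controls, 1, 5 and 3 for aspartic acid, glutamic acid and serine against polystyrene, and 2 for aspartic acid against serine. Among genes of above-median level, CDK inhibitors were 0.027 for aspartic acid against amino-terminated, and those 6 counts were 5, 12, 3, 7, 6 and 0. With the mean of all probe sets, the NRF2 list was 0.10 between the controls and 0 genes were 2-fold apart for glutamic acid against serine.

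At least 1.5-fold apart were 23, 36 and 505 genes for aspartic acid, glutamic acid and serine against amino-terminated, 301 between the controls, 129, 121 and 139 for the 3 against polystyrene, and 9, 310 and 70 for aspartic against glutamic acid, aspartic acid against serine and glutamic acid against serine. At least 3-fold apart were 0 genes for serine against amino-terminated, 4 between the controls, 0, 2 and 0 for the 3 against polystyrene, 0 for aspartic acid against serine and 0 for glutamic acid against serine. Leaving out 1 array, the class comparison gave 0 to 26 genes.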

Other observations

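The lists in the next 2 paragraphs and the counts of single arrays were chosen only after the results were seen, while each test was fixed before its own values were known.

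Lysosomal genes were higher on all 3 amino acid arrays than on the amino-terminated array, with medians of 0.14 on aspartic acid (26 of 33 higher, the hexosaminidase HEXA 0.51, the cholesterol carrier NPC2 0.45), 0.15 on glutamic acid (26 of 33, CLCN7 0.44) and 0.16 on serine (23 of 33, SCARB2 at most −0.68 with 0.10 from its other probe set, MCOLN1 0.60, inside the random range with the mean of all probe sets). Subunits of the vacuolar ATPase, the proton pump of lysosomes, had medians of 0.23, 0.11 and 0.12 with 11, 11 and 8 of 14 higher (ATP6V1B2 0.48 on aspartic acid), though the serine value was −0.07 on the values as deposited and −0.06 with equal medians, where the median of all genes was −0.12 and −0.11, and lay inside the random range under all 3 other scalings. The hypothesis that these genes were low on the amino-terminated array was tested in 4 comparisons without the genes that had prompted it. The vacuolar ATPase list lay beyond random lists in the predicted direction in 4 of them, including amino-terminated against polystyrene (median −0.20, 10 of 14 lower). The lysosomal list did so in 3, since it lay inside the random range between the controls (median −0.06, percentile 14.9). A lower level of these genes on that array may be a property of the surface or of the 1 array, which all 4 comparisons share.

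Genes that depend on ERK signalling were higher on all 4 prepared surfaces than on polystyrene, tested without DUSP6, ETV5 and MAFF. The list lay above random lists in 4 of 4 comparisons, with medians of 0.24 on amino-terminated (20 of 24 higher, EGR1 0.95, PLAUR 0.88), 0.27 on aspartic acid (18 of 24, EGR1 0.73), 0.32 on glutamic acid (20 of 24, PLAUR 0.92) and 0.18 on serine (18 of 23, EGR1 0.78). Higher ERK activity on the prepared surfaces is a hypothesis. ERK-dependent genes overlap the immediate early list fixed beforehand, with EGR1 in both, so this was not an independent test. The 4 comparisons share the polystyrene array.

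Single arrays were set against the other 4, where chance order gives 20% of genes in each direction. Polystyrene held 23 genes beyond all others by at least 1.5-fold, 7 higher (GPR176 and TMEM230 by 1.79-fold, NPPB by 1.77-fold) and 16 lower (GCLM by 2.16-fold, SLC7A11 by 1.86-fold). Serine held 20, of which 18 were higher (VSIG4 and VNN3P by 1.78-fold), and amino-terminated held 7, among them GCLM (1.62-fold), ASNS and CCN2 (1.57-fold) above and GPNMB (1.62-fold) below. Aspartic acid and glutamic acid held 0 each. By any gap, with both directions added, 50% of genes had serine at either end, 46.5% amino-terminated, 43.7% polystyrene, 29.7% aspartic acid and 20.7% glutamic acid. These totals compare with the chance shares of both directions together, below which aspartic acid and glutamic acid lay. The serine count was 8 on the values as deposited, 9 with equal medians, 31 with equal 75th percentiles, 7 with the floor at the 60th percentile, 33 without a floor, 2 with log2(value + 50) and 1 among genes of above-median level. The polystyrene count was 14 with the floor at the 60th percentile, 9 with log2(value + 50) and 13 among genes of above-median level, and the amino-terminated count lay between 5 and 10 under all 9 alternatives.

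For the 3 amino acid arrays against both controls, 0 genes passed the 1.5-fold gap, and the highest of the other splits gave 3. Since the real count was 0, all 10 splits reach it whatever the data, so the comparison of splits decides nothing here, and 10 splits could not give a share under 0.05 in any case.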
